A study of Mus musculus with 6 samples.

How the data were processed

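Gene expression was measured in 6 pools of cultured mouse embryos of the CD1 strain, an outbred stock. Per the labels' protocols, embryos were collected at embryonic day 5.0, just after implantation, and cultured for 8 hours in cavities of 90 or 180 µm diameter. Each sample pooled 30 whole embryos, and its total RNA was labelled with biotin for hybridization to an Affymetrix Mouse Gene array. The 2 groups held 3 samples each, named here narrow 1 to 3 and wide 1 to 3 after the replicate numbers of the titles. The design text calls them biological replicates, so p-values of single genes measure the spread between pools of embryos and not between single embryos.

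The deposited values were log2 signals, 1 per array feature and sample, between 4.33 and 14.31. The log2 scale was read from this range. Background correction, summarization, normalization and software are not given in the sources used here. The 6 arrays had nearly equal distributions, with medians from 7.62 to 7.67, so the values had been normalized between arrays before deposit and were used without further scaling. Such scaling removes any change in total RNA per embryo. Signals of different genes depend on their probes and were not compared with each other. No measure of background came with the values, so dim genes could not be told from absent ones, and the number of arrays limits the precision.

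Genes were named through the platform annotation. Of 28853 array features, 21789 named 1 gene, 1621 named several and 5443 named none. The 21789 features covered 19938 genes, and the Entrez gene identifiers of 21698 of them were found in a RefSeq gene table, which changed 0 symbols. For the 999 genes with more than 1 feature, the feature with the highest mean over the 6 arrays was used, and no filter on dim genes was applied. The 7064 features naming no gene or several were tested in a fit over every feature only. The build behind the array's design is not given in the sources used here, so gene positions were not analysed here.

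Differences between cavities (narrow minus wide) were tested for each gene with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with default settings, two-sided, on all 6 arrays with no covariate. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Differences carry the standard error of the limma fit, and group means carry the SD. A single gene compared on its own by an exact permutation test of 3 against 3 samples cannot reach a p below 0.1. Sets of genes were tested with camera, which asks whether a list's genes moved more than other genes, adjusted over 28 lists. The correlation between genes was preset to 0.01. Its p then takes genes and not pools as the units, although the statistic of each gene uses the spread between pools. Further set tests were camera with the correlation estimated for each list, and fry. The directional p of fry tests whether a list's genes move one way on balance, its mixed p whether they change in either direction, and neither compares a list with other genes. A mean difference over a list has a 95% interval from the spread of the 6 array means of that list. In members of a list, p-values were also adjusted over the list alone.

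The groups, the tests, the 28 lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists held 382 entries, of which 360 were measured, and 17 genes were in more than 1 list. Named genes were, in each direction, those with the largest difference past the adjusted threshold and, as too few passed, those with the smallest unadjusted p up to 10, leaving out predicted, olfactory, vomeronasal and small RNA genes. Every measured member of the distal and anterior visceral endoderm list was named as well. From every other list came up to 4 members that passed, or otherwise up to 2 with the smallest p, and up to 4 members of a list past the threshold. Any other gene named was chosen after its values were seen.

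Whether the replicate numbers pair the samples was checked from the deviations of each array from its group mean over all genes. These deviations correlated at 0.516 between narrow 1 and wide 1, 0.176 for the arrays numbered 2 and 0.272 for those numbered 3. All 3 values exceeded 0.1, so the numbers were taken to pair the samples, although the labels do not say what a number stands for. The closest other pair was narrow 2 with wide 3, at 0.178, above the 0.176 of the arrays numbered 2. Deviations within a group cancel out, so arrays numbered 1 that stand apart also raise the correlations between the others. The pairing is thus clear for number 1 only. Counts over same-numbered pairs, their intervals, splits by pairs and the block all rest on it. A fit with the replicate number as a block was run beside the unblocked one.

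The gene and list tests were tested on simulated data made from the gene means and residual SDs of these arrays with 200 of 19938 genes changed, 20 times. The simulated noise was independent between genes and arrays and lacked the structure of the arrays numbered 1. The rates may therefore overstate what the tests recover in the real data. In this comparison limma recovered 34.7% of genes changed by 0.25 on the log2 scale, 83.4% at 0.5, 98.7% at 1 and 99.8% at 2. Of its calls 4.06% lay outside the 200 genes, a share that also counts calls of the 12 list members shifted in the same runs. A list whose 12 members were all shifted by 0.15 was called in 100% of runs by camera with the preset correlation, 0% with an estimated correlation and 70% by fry. Alternatives covered filters on dim genes, normalization, the feature taken per gene, the variance model, an offset of 16 on the linear scale, other tests and leaving out each array. Figures were drawn with matplotlib 3.10.9.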

Results

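Transcript levels were compared between mouse embryos grown for 8 hours in narrow cavities of 90 µm and in wide cavities of 180 µm diameter. Around the time of collection, embryonic day 5.0, the distal visceral endoderm forms at the tip of the egg cylinder, a group of cells that later marks the anterior side. The series asked how embryos cultured with and without external mechanical cues differ. Its design text does not say outright which cavity gives the cue, and its word order pairs the narrow one with the cue. Each cavity had 3 samples of 30 pooled whole embryos, so epiblast, extraembryonic ectoderm and visceral endoderm were measured together. Array medians lay between 7.62 and 7.67 on the log2 scale. Every pair of arrays correlated at 0.998 or more over genes, which are not independent replicates.

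Of 12 markers of the distal and anterior visceral endoderm, all measured, 4 rose in narrow cavities when adjusted over the list alone, 0 fell and 8 did not pass, 4 of these with negative differences. Cer1, a secreted inhibitor of Nodal, BMP and Wnt, rose 1.62-fold from a log2 signal of 9.03 ± 0.19 in wide to 9.73 ± 0.23 in narrow cavities (SD, n = 3 each). Lefty1, an inhibitor of Nodal made by the same cells, rose 1.24-fold from 7.12 ± 0.06 to 7.43 ± 0.07. Fzd8, a Wnt receptor, rose by 0.33 ± 0.08 (SE) on the log2 scale and Lhx1, a transcription factor needed for head formation, by 0.15 ± 0.05. All 3 narrow samples lay above all 3 wide samples for each of these 4 genes. Genes picked for a small p tend to separate in this way, so it is no further support.

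With limma and Benjamini-Hochberg adjustment over the list alone, adjusted p was 0.00329 for both Cer1 and Lefty1, 0.0159 for Fzd8 and 0.0457 for Lhx1. When each array was left out in turn, Cer1 and Lefty1 passed in 6 of 6 fits, Fzd8 failed without narrow 3, wide 1 or wide 2 (adjusted p from 0.0547 to 0.0642), and Lhx1 passed only without narrow 2 (elsewhere 0.0521 to 0.130). Over all 19938 genes 0 of the 12 passed. With the replicate number as a block, 2 more members passed over the list alone, the Wnt inhibitor Sfrp1 (0.14 ± 0.05, adjusted p = 0.0284, without the block 0.0524) and the endoderm factor Foxa2 (0.13 ± 0.06, adjusted p = 0.0284, without the block 0.127). The other members had differences near 0, namely Hhex at 0.03 ± 0.07, Otx2 at 0.03 ± 0.11, Gsc at -0.02 ± 0.06, Sfrp5 at -0.03 ± 0.06, Dkk1 at -0.06 ± 0.04 and Hesx1 at -0.09 ± 0.17. Lefty2, a close paralog of Lefty1, had a difference of -0.11 ± 0.10.

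As a group, the 12 markers had a median difference of 0.082 and a mean of 0.13 (95% interval 0.015 to 0.25), higher in narrow in 3 of 3 same-numbered pairs. Camera gave an adjusted p of 0.000250 over 28 lists, and adjusted p = 0.149 with an estimated correlation. The estimate was -0.032, below the preset 0.01, so a higher correlation between members was not what cost the call. With an estimated correlation camera called a simulated list shifted by 0.15 in 0% of runs, so its lack of a call does not decide. The fry test gave an adjusted p of 0.295 for movement in 1 direction and 0.00858 for change in either direction. In the simulation fry called the shifted list in 70% of runs, so its lack of a call in 1 direction carries more weight. Markers of visceral endoderm in general, such as the transferrin gene Trf (0.18 ± 0.05) and the retinol carrier Rbp4 (0.18 ± 0.09), had a mean difference of 0.020 (95% interval -0.027 to 0.068) with 9 of 20 positive, and 0 passed over the list alone (camera adjusted p = 0.710). The call on the 12 markers ended without narrow 1 (median 0.063, adjusted p = 0.0611) and without Cer1 and Lefty1 (median 0.029, adjusted p = 0.139). Among genes above the median signal only, which leaves out Lefty1, the list's median was 0.030 (adjusted p = 0.0268).

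**Figure D1:**
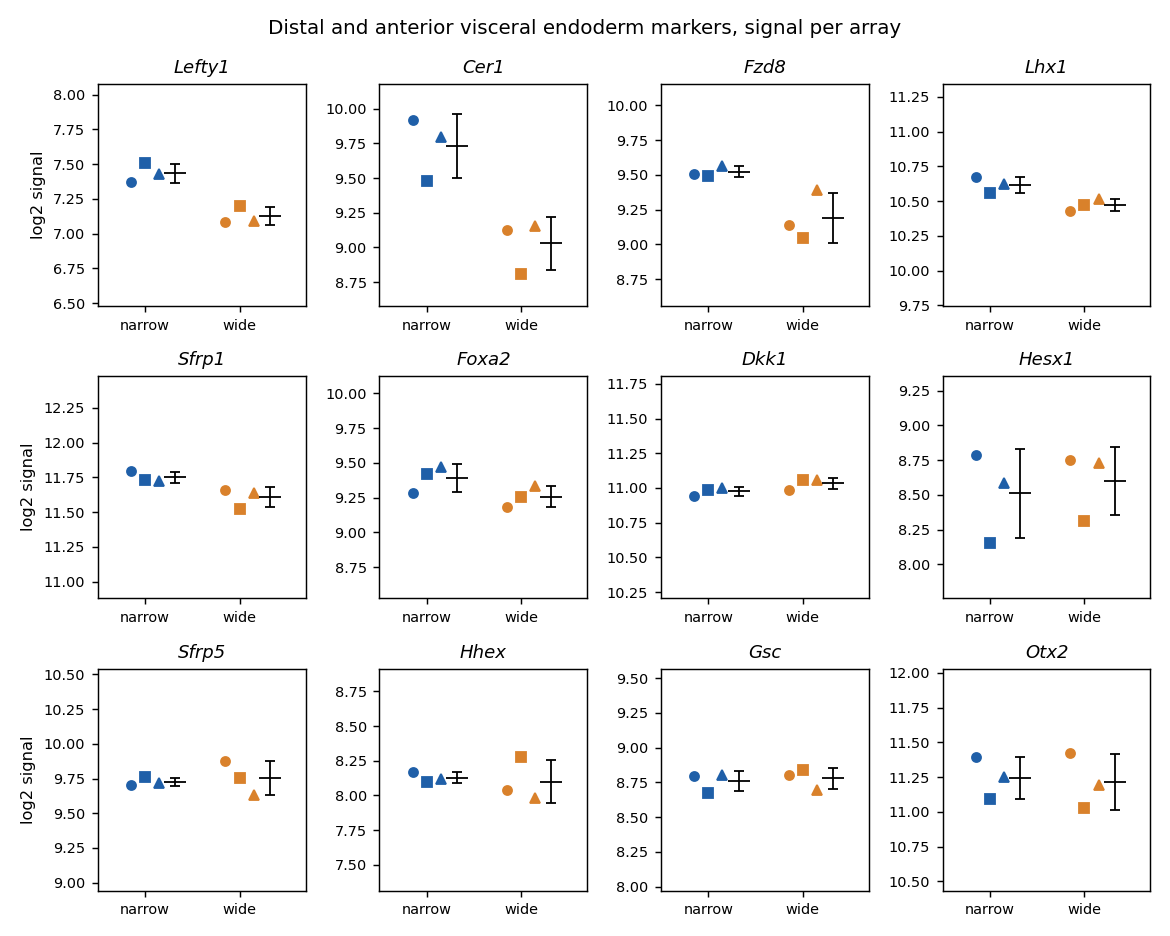
Log2 signal of the 12 distal and anterior visceral endoderm markers in narrow (blue) and wide (orange) cavities, with circles, squares and triangles for samples 1, 2 and 3, and the group mean with its SD beside them. Every panel spans the same log2 range, and the narrow samples of Cer1, Lefty1, Fzd8, Lhx1 and Sfrp1 all lie above the wide ones.

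Among 13 genes of the unfolded protein and amino acid response, 1 rose in narrow cavities when adjusted over the list alone, 0 fell and 12 did not pass, with 11 of the 13 differences positive. Trib3, a pseudokinase induced by the transcription factor Atf4, rose by 0.25 ± 0.06 (adjusted p = 0.0354 with limma, adjusted over the list alone). Chac1, an enzyme that degrades glutathione, had a difference of 0.26 ± 0.08 (adjusted p = 0.0745) and passed over the list alone with the replicate number as a block (adjusted p = 0.0131). Sesn2 at 0.11 ± 0.05 and Ddit3 at 0.09 ± 0.05 did not pass. Some members lay near 0 in the same-numbered pairs 1, 2 and 3. Among these were Hspa5 (-0.001, 0.031 and 0.019), Xbp1 (-0.027, 0.012 and -0.0001) and Asns (0.006, 0.001 and -0.031). The list thus did not rise evenly. All narrow samples lay above all wide samples for 5 members, where chance gives 5% of genes in this direction. The median difference was 0.052 and the mean 0.083 (95% interval 0.049 to 0.12). Camera gave an adjusted p of 0.000175, and adjusted p = 0.149 with an estimated correlation, the estimate being -0.030. Fry gave an adjusted p of 0.0408 for movement in 1 direction and 0.0918 for change in either direction. Trib3 did not pass without narrow 2, narrow 3, wide 1 or wide 3 (adjusted p from 0.0765 to 0.141 over the list alone). Without wide 2 the list's median was 0.085 (camera adjusted p = 5.24e-05).

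**Figure D2:**
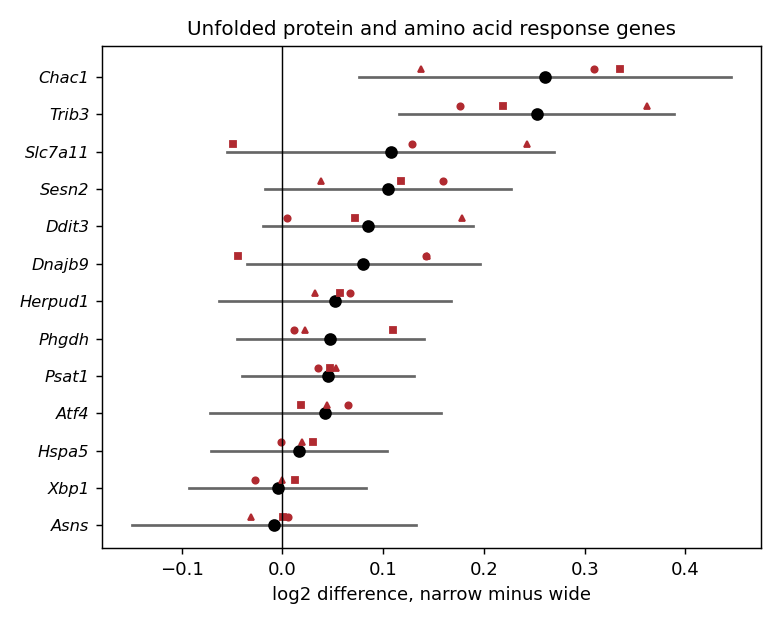
Log2 differences, narrow minus wide, of the 13 unfolded protein and amino acid response genes. Black points and bars are the limma estimate with its 95% interval, and small red circles, squares and triangles are the differences between samples numbered 1, 2 and 3. Chac1 and Trib3 lie farthest to the right, at 0.26 and 0.25.

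In the lists of pluripotency and epiblast genes, Esrrb, an orphan nuclear receptor listed with naive pluripotency, fell by 0.22 ± 0.04 on the log2 scale (limma adjusted p = 0.0118, adjusted over the list alone). Esrrb was the 1 of 11 naive genes to pass, and pools of whole embryos do not show in which tissue it fell. It did not pass without narrow 3, wide 1 or wide 2 (adjusted p from 0.0513 to 0.0585). Tbx3, from the same list, had a difference of -0.09 ± 0.05, and the naive list as a whole was not called (camera adjusted p = 0.979). The 10 core pluripotency genes had a mean difference of -0.053 (95% interval -0.078 to -0.029) with 7 negative, including Sox2 at -0.09 ± 0.05 and Nanog at -0.16 ± 0.09, and 0 passed over the list alone. Camera did not call this list (adjusted p = 0.128, and adjusted p = 0.538 with an estimated correlation), whereas fry did for movement in 1 direction (adjusted p = 0.0408). Among genes above the median signal, camera called it as well (adjusted p = 0.0268). Of the 12 post-implantation epiblast genes 0 passed (camera adjusted p = 0.558), although Sox4, at 0.22 ± 0.07, did so over the list alone with the replicate block (adjusted p = 0.00902, without the block 0.131). The other member with a small p was Foxd3, at 0.12 ± 0.06.

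In the extraembryonic ectoderm list, 0 of 13 members passed over the list alone (camera adjusted p = 0.814). Its member Bmp4, the ligand that patterns the proximal epiblast, had a difference of -0.21 ± 0.08 and passed over the list alone only with the replicate block (adjusted p = 0.0127, without the block 0.298). Bmp8b stood at -0.09 ± 0.05. Among BMP response genes Id1 had -0.14 ± 0.06 and Smad6 -0.13 ± 0.06, and 0 of 10 passed (camera adjusted p = 0.199). Of the 15 measured Nodal pathway genes 2 rose, 0 fell and 13 did not pass over the list alone (camera adjusted p = 0.292). The 2 were Cer1 and Lefty1, which both lists share. Among primitive streak and mesoderm genes, Mixl1 had a difference of -0.14 ± 0.04 (adjusted p = 0.0571 over the list alone) and 0 of 11 passed (camera adjusted p = 0.293). Wnt response genes (camera adjusted p = 0.973, Ccnd1 at 0.13 ± 0.08) and FGF and ERK response genes (0.814, Phlda1 at -0.10 ± 0.05) had 0 members past the list-alone threshold.

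Lists that follow mechanical load on cells were not called. The 23 YAP and TEAD targets had a median of 0.030 (camera adjusted p = 0.530), with the matricellular protein Ccn2 at 0.12 ± 0.05 and Nt5e at -0.19 ± 0.09. For 17 actin cytoskeleton genes driven by SRF and MRTF the median was 0.034 (adjusted p = 0.247), with Tagln at 0.13 ± 0.05 and Actg2 at 0.11 ± 0.05. The 15 immediate early genes had a median of 0.0025 (adjusted p = 0.558), with Ier2 at 0.15 ± 0.05. Camera adjusted p was 0.713 for basement membrane genes (Lama1 at -0.05 ± 0.04), 0.979 for matrix proteases and their inhibitors (Mmp11 at -0.11 ± 0.04), 0.293 for epithelial junction and keratin genes (Crb3 at 0.06 ± 0.04) and 0.979 for epithelial to mesenchymal transition genes. In each of these 7 lists 0 members passed over the list alone.

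Lists of markers of other cell types were not called either. Camera adjusted p was 0.293 for trophoblast giant cell and ectoplacental cone markers, of which 6 of 10 were measured, 0.710 for parietal endoderm markers (Thbd at 0.13 ± 0.06), 0.710 for maternal decidua and stroma and 0.979 for blood cells. Lyz2, a gene of macrophages, had a difference of -0.41 ± 0.32 with an SD of 0.73 among wide samples. Of the stress and metabolic lists, hypoxia and glycolysis genes (adjusted p = 0.979) held Ddit4, an inhibitor of mTORC1, at 0.28 ± 0.07, which passed over the list alone only with the replicate block (adjusted p = 0.0102, without the block 0.0808), and Vegfa at -0.11 ± 0.04. Heat shock genes (adjusted p = 0.558, Hspa1a at 0.09 ± 0.04), p53 targets (0.979), cell cycle genes (0.710) and cholesterol synthesis genes (0.979) had 0 members past the list-alone threshold. In 5 lists, none of them called, the signs of the median, the mean and the tests were not all alike: general visceral endoderm, naive pluripotency, hypoxia and glycolysis, p53 and cholesterol synthesis.

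**Figure D3:**
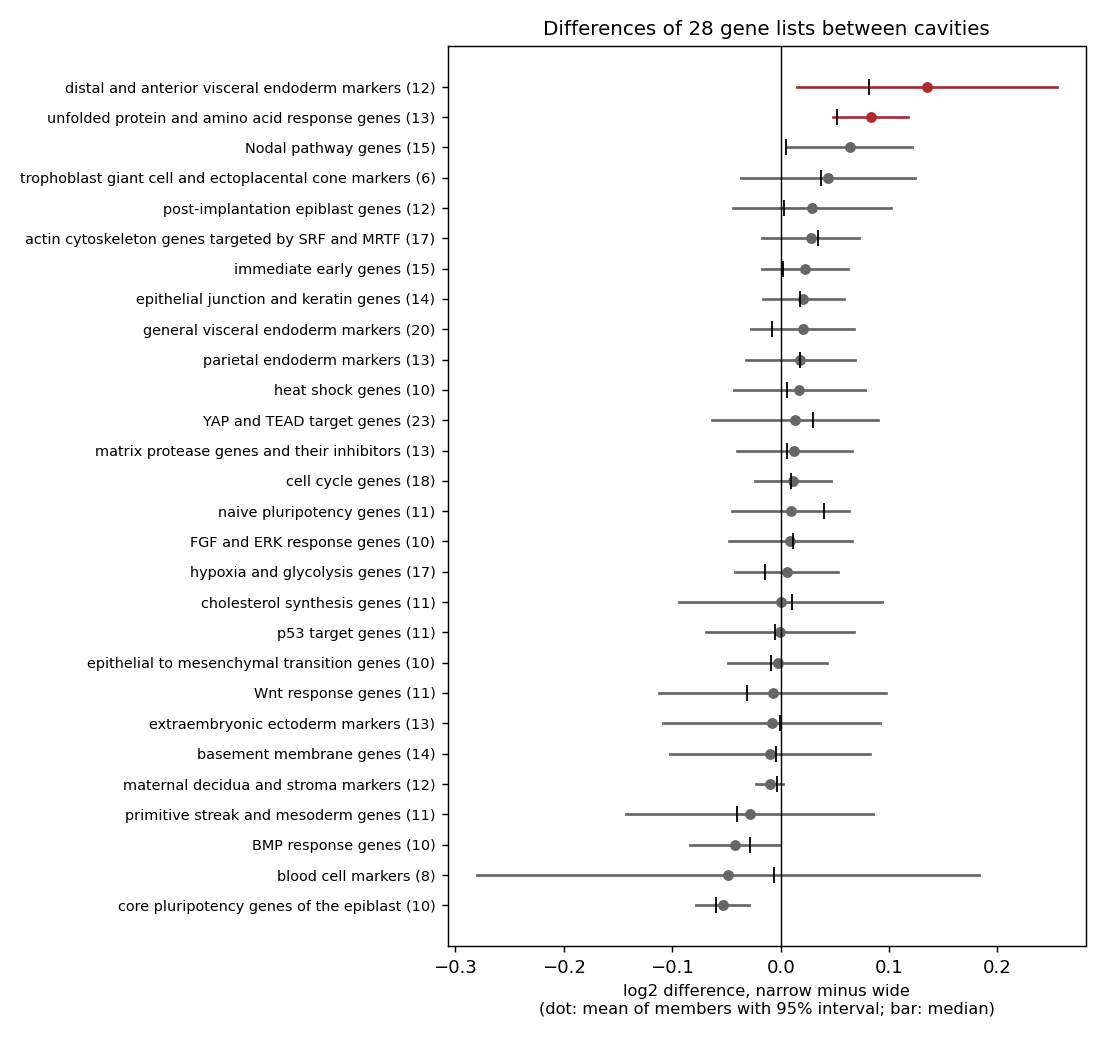
Mean log2 difference, narrow minus wide, of each of the 28 gene lists with its 95% interval from the spread between arrays (dots and lines), and the median over members (black bars), with the number of measured genes in parentheses. The 2 lists in red, at means of 0.13 and 0.083, passed camera with the preset correlation and neither did with an estimated one (adjusted p = 0.149 for both). With an estimated correlation a simulated shifted list was called in 0% of runs.

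Across all 19938 genes, those with the smallest unadjusted p that were higher in narrow cavities were Lefty1, the chemokine receptor Cxcr4 (0.25 ± 0.04), the secreted kinase Pkdcc (0.25 ± 0.04), the Kit ligand gene Kitl (0.24 ± 0.04) and Cer1. Next came Senp8 (0.34 ± 0.07), the Wnt receptor Fzd5 (0.32 ± 0.07), Fcamr (0.20 ± 0.04), the erythroid factor Gata1 (0.29 ± 0.07) and Slc35d3 (0.20 ± 0.05). Those lower in narrow cavities were Gramd4 (-0.24 ± 0.04), Capza3 (-0.21 ± 0.04), the interferon-induced Oasl2 (-0.24 ± 0.04), the lipoprotein receptor Vldlr (-0.25 ± 0.05), Esrrb and the hyaluronan synthase Has2 (-0.21 ± 0.04). They were followed by Gml (-0.26 ± 0.05), Gbp8 (-0.27 ± 0.06), Krtap10-10 (-0.17 ± 0.04) and Defb34 (-0.26 ± 0.06). None of these 20 passed over all genes. Cer1 had the largest positive difference of any gene, and the largest in either direction was that of Cacna1f at -0.74 ± 0.55, whose narrow samples had an SD of 1.32.

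By limma with Benjamini-Hochberg adjustment, 0 of 19938 genes passed, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 678 genes, 335 higher and 343 lower in narrow, where 996.9 are expected by chance. A test per gene with unequal variances called 0 after adjustment and 477 without. With the replicate number as a block, 0 passed again, the smallest adjusted p was 0.0838, that of Cer1, and 1446 genes had an unadjusted p under 0.05. Cer1 was the 1 gene with both an unadjusted p under 0.05 and a difference of 1.5-fold or more. All narrow samples lay above all wide samples for 831 genes and below them for 705, together 7.70%, where chance gives 10%. The median standard error over genes was 0.053, or 0.040 with the block.

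The arrays numbered 1 stood apart from the rest, whichever the cavity. The first principal component, with 38.5% of the variance, placed narrow 1 and wide 1 at -10.6 and -8.01 and the other 4 arrays between 2.76 and 5.87. With those 4 arrays alone, 0 genes passed and 914 had an unadjusted p under 0.05. The distal visceral endoderm list then had a median of 0.077 (camera adjusted p = 0.0235) and the unfolded protein and amino acid response list 0.050 (0.0198). Neither was called in these 4 arrays with an estimated correlation (adjusted p = 0.812 for both). That test called a shifted list in 0% of simulated runs with 6 arrays, so this result does not decide.

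**Figure D4:**
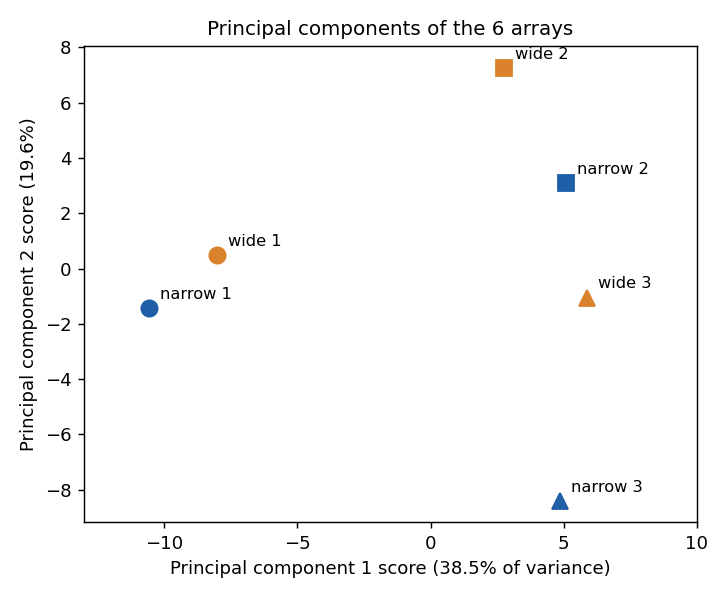
Scores of the 6 arrays on the first 2 principal components over all genes, in log2 units, with the share of variance on each axis, narrow in blue and wide in orange. Narrow 1 and wide 1 (circles) lie at the left, at -10.6 and -8.01, and the other arrays at the right.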

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

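The fits on the 4 arrays numbered 2 and 3, on lists without single members and of list-alone calls without each array were chosen after the data were seen. By limma 0 genes passed under every alternative, with 1 exception made without adjustment, where unadjusted p with a 1.5-fold difference gave 1 gene, Cer1. The 678 genes at unadjusted p under 0.05 became 384 above the 50th percentile of signal, where fewer genes were tested, and 1446 with the replicate number as a block. Leaving out each array gave 497 to 990. The block changed no other call than those of single members named in the report, where 12 genes in place of 6 passed over a list alone. With it, camera gave adjusted p = 0.000668 for the distal visceral endoderm list and 0.000658 for the unfolded protein and amino acid response list, and adjusted p = 0.705 for both with an estimated correlation. The 2 called lists became 0 with an estimated correlation, 3 above the 50th percentile of signal and 1 to 2 when each array was left out, 1 without narrow 1. A call lost with an estimated correlation decides little, as that test called a shifted list in 0% of simulated runs. The distal visceral endoderm list kept its median of 0.082 but lost its call with an estimated correlation (adjusted p = 0.149) and with fry (0.295). It ranged from 0.063, without narrow 1, to 0.11 when each array was left out, and was 0.029 without Lefty1 and Cer1 (adjusted p = 0.139) and 0.030 without Lefty1 alone (0.00976). Its adjusted p over 20 alternatives ran from 1.49e-05 to 0.295. The unfolded protein and amino acid response list had a median of 0.052 and lost its call with an estimated correlation (adjusted p = 0.149). It ranged from 0.047 to 0.085 when each array was left out and stayed called without Trib3 and Chac1 (0.048, adjusted p = 0.0173), with an adjusted p from 3.20e-05 to 0.149 over 20 alternatives. Causes of these changes were not tested where not stated. Of 1316 values of 84 genes, 1306 kept their sign and side of the threshold and 10, none called, changed sign. Leaving out 1 array moved 38 of the 84 by over 1.5 times at least once, 0 of them among the 6 called over a list alone, for example Nanog (-0.26 to -0.09) and Sox2 (-0.12 to -0.05). Of 467 medians of the other 26 lists, 407 did so, 58 uncalled ones changed sign and 2 were newly called, both of core pluripotency genes (adjusted p = 0.0268 above the 50th percentile of signal and 0.0408 with fry). Dim genes are limited by array background, which was not measured, and Lefty1 lay at the 38.9th percentile of signal.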

Other observations

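The tests of visceral endoderm share, of other stress genes and of epiblast progress were chosen after the results were seen.

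The distal visceral endoderm list had a median difference of 0.082 on the log2 scale, called by camera with the preset correlation but not with an estimated one (adjusted p = 0.149). With an estimated correlation a simulated shifted list was called in 0% of runs, so that result does not decide. Fry called the simulated list in 70% of runs but did not call the real one for movement in 1 direction (adjusted p = 0.295). For change in either direction fry gave adjusted p = 0.00858. A larger share of visceral endoderm in the narrow pools cannot be told apart from a change within that tissue, because the list's mean exceeded that of general visceral endoderm markers by 0.11 with a 95% interval of -0.034 to 0.26, or -0.012 to 0.24 from the 3 same-numbered pairs, all positive. On the other side, general markers had a median of -0.0077 with 11 of 20 negative. The 10 splits of the 6 arrays are too few for a share under 0.05, with 1 as large, 0.082 for the real split and 0.079 for the highest other, while the 3 others of 4 that part all same-numbered pairs reached 0.049. A response of these cells to the cavity may be at work, as a hypothesis that these data leave open.

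The unfolded protein and amino acid response list had a median difference of 0.052, likewise not called with an estimated correlation (adjusted p = 0.149). The list's mean exceeded that of 53 heat shock, p53, hypoxia and immediate early genes by 0.072 (95% interval 0.022 to 0.12 from the spread between arrays and 0.021 to 0.12 from that between genes). Those 53 genes had a mean of 0.011 (95% interval -0.0051 to 0.028), so as a set they moved little. The list was examined because camera had called it while their lists were uncalled. An excess over them was therefore likely beforehand and does not decide on a general stress response. The 10 splits are too few for a share under 0.05, with 1 as large, 0.052 for the real split and 0.042 for the highest other. A response to nutrient supply or to confinement in the narrow cavity may be a cause, which was not tested.

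Narrow 1 and wide 1 stood apart from the other 4 arrays, with deviations that correlated at 0.516. The correlation was 0.487 after quantile normalization and 0.523 without small RNA and predicted genes, which argues against a difference in the spread of signal or in those genes as the whole source. By limma, 1 gene, Mir377, passed between these 2 arrays and the other 4 (1.00 higher, adjusted p = 0.0205), and 4161 genes had an unadjusted p under 0.05 against 1007 and 1429 for the numbers 2 and 3. The contrast was chosen after these arrays had stood apart, so its p-values describe that structure and do not test it. In the fits for numbers 2 and 3 the arrays numbered 1 were among the rest and widened the spread. The gene lists were also tested between the arrays numbered 1 and the other 4, and 0 passed the adjusted threshold. The lack of a call names no listed cell type, pathway or stress response as a source and excludes none. Camera compares a list with the other genes, and its power in this contrast was not simulated. Biological explanations outside the lists were not tested. A difference between batches of embryos, RNA or arrays stays open, as the labels name none.

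For counts of genes the 10 splits are likewise too few. All 10 gave 0 genes, so the real 0 equalled the highest other, and 1 split, the real one, gave as many as 2 lists, the highest other being 0. At unadjusted p under 0.05, 5 splits gave 678 genes or more, and the highest other was 2640, in the split of narrow 1, wide 1 and wide 2 from the rest. That split keeps the arrays numbered 1 together, which points to the structure that sets these apart. Among the 4 splits that part all 3 same-numbered pairs, the real one had the most, against 668, 414 and 357.

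A shift from naive to post-implantation epiblast was tested as a hypothesis. The mean difference of the post-implantation list minus that of the naive list was 0.020 (95% interval -0.034 to 0.074, or 0.011 to 0.029 from the same-numbered pairs), while the difference of their medians was -0.037. Members of both lists went both ways, so these values leave the hypothesis open.

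Sex-linked genes, chosen after their values were seen, differed between pools, most in narrow 2. Uty, which is Y-linked, was higher in all narrow than in all wide samples (0.15 ± 0.05 SE, limma adjusted p = 1.00 over all genes). In 3 of 3 same-numbered pairs Eif2s3y was higher in narrow (0.13 ± 0.07) and Xist lower (-0.30 ± 0.18), and Kdm5d was higher in 2 of 3 (0.10 ± 0.07). Narrow 2 had a log2 signal of 10.52 for Xist, with 11.03 to 11.50 in the other 5 pools, and 9.58 for the Y-linked Eif2s3y, with 9.24 to 9.36 in the others.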
